A study of Mus musculus with 24 samples.

How the data were processed

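Poly(A) RNA was sequenced from pancreatic tumour-derived mouse cell lines with a strand-specific library kit, per the labels' protocols, in 24 libraries of 8 mice that share 1 batch label. Per the submitters' processing notes, Trim Galore 0.6.4, FastQC, STAR 2.7.3a, HTSeq 0.9.1, SAMtools 1.16 and DESeq2 were used with the mm10 build. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are a normalized signal per gene, not raw counts, made by the authors as read counts divided by a DESeq2 size factor per column, per the labels and the values themselves. The table holds 48439 gene IDs in 8 columns, 1 per mouse. The labels of the 3 libraries of a mouse name the same column, so they were merged by the authors, and how is not given in the sources used here. The spread between libraries of a mouse could therefore not be measured, and p-values measure the spread between lines from different mice.

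In each column 100% of the values were whole multiples of the smallest value, within a tolerance of 0.01 reads. Whole reads were recovered by this step, and the reciprocals of the steps equalled median-of-ratios size factors of the recovered reads. Recovered reads totalled 105009817 to 127165560 per mouse. The floor for a gene with no read was set at 3 reads per mouse, and it covers counting error only, since reads of a library amplified by PCR are not independent molecules. No pair of columns agreed within sampling noise. Gene IDs were paired with names and mm10 positions from GENCODE M21 by stable ID. Of the IDs, 48057 had a name, and the 382 without one held at most 0.017% of any column. Gene values were not corrected for length. Reads shared with near-identical copies were not resolved.

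The tests were run on log2(normalized count + 1) per mouse, and fold changes are on that scale, which understates changes of low genes. Genes with a normalized count of at least 10 in at least 3 mice were tested, 16729 of the 27499 with any read. The gene test was limma 3.58.1 with a trend in eBayes and Benjamini-Hochberg adjustment, threshold 0.05. Gene lists were tested with camera at a preset correlation of 0.01, over the 33 of 35 lists with at least 5 tested members, beside camera with an estimated correlation, camera on ranks and fry. The fry p tests whether members move on balance in a single direction. A list score per mouse was the mean of centred log2 values of the members. Scores, single genes, the separation of the genotypes (PERMANOVA pseudo-F on Euclidean distances) and the spread within a genotype used exact permutation tests over all 56 splits of the mice into 3 and 5. The smallest possible p is 0.0179. The interval of the target genes is a 95% interval from a linear model.

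Lists, tests and the rule for named genes were set before the data were examined. The rule takes Kmt2d, Kras and Trp53, then for each direction the 12 genes with the largest change among those past the threshold whose groups do not overlap and whose higher mean is at least 50. Where fewer pass, the genes with the smallest unadjusted p under the same conditions fill the places. For each described list it takes up to 4 members with the smallest unadjusted p. Predicted genes are counted and not placed among the 12. Gm14150, which passed, and Cenpf, a further G2/M gene past the threshold over its list alone, were named outside this rule after the results were seen. Alternatives were pseudocounts of 0.5 and 8, no filter, a mean of at least 100, equal totals, quantile normalization, array weights, robust eBayes, leaving out each mouse, and edgeR 4.0.16 quasi-likelihood, DESeq2 1.42.0 and limma voom on recovered reads. A library-level model was not run, because the libraries of a mouse share a column. R 4.3.3 was used, with BLAST+ 2.17.0 to match pseudogenes to coding transcripts.

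The functions were tested on simulated data for the comparison of KPC Kmt2df/+ with KPC, with counts drawn for 16729 genes at the spread between these lines and 200 genes changed. Limma recovered 5 of 50 genes changed 2-fold, 27 of 50 changed 4-fold, 37 of 50 changed 16-fold and 48 of 50 changed 64-fold, with 10 false calls among 127. DESeq2 made 110 false calls among 253 in the same simulation, and edgeR made 10 among 125. With the dispersion lowered to 0.1 of this, limma recovered 32 of 50 genes changed 2-fold.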

Results

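RNA sequencing measured gene expression in cell lines grown from pancreatic tumours of 8 genetically engineered mice. KPC is the usual name for mice whose pancreas carries an activated Kras together with an altered Trp53, and the labels do not say which alleles were used. Lines from 3 KPC mice were compared with lines from 5 KPC Kmt2df/+ mice, a notation usually read as a conditional Kmt2d allele beside a normal one. Kmt2d encodes a histone H3 lysine 4 methyltransferase that acts at enhancers. The cells were cultured under basal conditions, and the labels list 3 libraries for each mouse, 9 for KPC and 15 for KPC Kmt2df/+. The deposited table holds 1 column per mouse, so the mouse was the replicate in every test. Reads assigned to genes ranged from 105009817 to 127165560 per mouse. Values are given as DESeq2-normalized counts, mean ± SD over mice, with n = 3 for KPC and n = 5 for KPC Kmt2df/+ throughout.

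The first question was whether the targeted gene differed in level. Kmt2d (mm10 chromosome 15, 98831669 to 98871204, minus strand) measured 6834.8 ± 2280.6 in KPC lines and 5963.7 ± 667.2 in KPC Kmt2df/+ lines. The log2 difference was -0.15, with a 95% interval of -0.68 to 0.37 (exact two-sided permutation p = 0.607). The single highest value, 9442.8, belonged to KPC mouse 3622, and without that mouse the difference was 0.10. The labels do not say which exons the modified allele lacks after recombination, and a count over the whole gene can include reads from a shortened transcript, so this level does not check the genotype labels. Kras (chromosome 6, 145216699 to 145250239) measured 15053.3 ± 2407.6 and 21760.6 ± 6697.1, a log2 difference of 0.49 (exact permutation p = 0.143). Trp53 (chromosome 11, 69580359 to 69591873) measured 1423.5 ± 301 and 1196.8 ± 195.1, a log2 difference of -0.24 (exact permutation p = 0.196). None of the 3 differences exceeded the spread between lines.

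The second question was which genes differed between the genotypes. Glt1d1, Jph1, Khdrbs3 and Fkbp10 rose in KPC Kmt2df/+ lines, as did the tubulin pseudogene Gm14150, and Aldh3a2 fell. Glt1d1, which encodes a glycosyltransferase-like protein (chromosome 5, 127632262 to 127709374), had no read in any KPC mouse and 559 ± 388.4 normalized counts in KPC Kmt2df/+ lines. This was at least 186.1-fold higher against a floor of 3 reads per KPC mouse (limma adjusted p = 0.00619). Jph1, a junctophilin that links the plasma membrane to the endoplasmic reticulum (chromosome 1, 16964560 to 17097889), was likewise without a read in KPC mice and measured 720.1 ± 861, at least 239.8-fold higher (limma adjusted p = 0.0167). Mouse 2940 carried much of this mean, which was 343.1 without it, at least 114.3-fold higher. Khdrbs3, an RNA-binding protein of the STAR family (chromosome 15, 68928420 to 69101211), measured 2.9 ± 2.5 and 3014.7 ± 3188.9, a log2 difference of 9.42 ± 0.88 (SE) (limma adjusted p = 0.0167), and the second mean was 1615.9 without mouse 2940.

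Fkbp10, a prolyl isomerase of the endoplasmic reticulum that takes part in collagen folding (chromosome 11, 100415697 to 100424824), rose from 1378.4 ± 335.9 to 11651.1 ± 3558.4, a log2 difference of 3.05 ± 0.29 (limma adjusted p = 0.0167). Gm14150 (chromosome 2, 151458956 to 151460309) rose from 98.4 ± 10.2 to 1253 ± 255.6, a log2 difference of 3.63 ± 0.26 (limma adjusted p = 0.00619). Its sequence matches Tuba1b at 98.6% identity, so reads of the tubulin gene and of the pseudogene may not be told apart, and its level is uncertain. Aldh3a2, a fatty aldehyde dehydrogenase (chromosome 11, 61223417 to 61267464), fell from 20885 ± 2449 to 8815.5 ± 997.4, a log2 difference of -1.25 ± 0.14 (limma adjusted p = 0.0419). In all 6 genes every KPC Kmt2df/+ mouse lay on the same side of every KPC mouse.

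Each of these calls was lost when some single mouse was left out. Leaving out a mouse also leaves fewer mice to test, so a lost call does not by itself show that this mouse carried it. The log2 differences of the 6 genes kept their direction in every other setting where they were tested. They ranged from -1.35 to -1.19 for Aldh3a2 and from 5.84 to 12.5 for Jph1. Gm14150 and Glt1d1 did not pass without KPC mouse 12278 (limma adjusted p = 0.0734 for both), nor Glt1d1 without KPC mouse 3622 (0.0506). Jph1 was lost without KPC mouse 2974 (0.0825), 12278 (0.106) or 3622 (0.108) and without KPC Kmt2df/+ mouse 2500 (0.0541). Khdrbs3 was lost without mouse 2974 (0.0568), 12278 (0.106), 3622 (0.085), 2500 (0.0541) or 12352 (0.0838). Fkbp10 was lost without mouse 2974 (0.0825), 12278 (0.106), 3622 (0.0849), 2500 (0.0504) or 2940 (0.0542). Aldh3a2 was lost without any single mouse, with limma adjusted p from 0.0541 without mouse 2500 to 0.213 without mouse 3622. Aldh3a2 was also lost with no filter, where the 5 genes that passed were all higher. Pseudocount 8 kept 5 of the 6 genes, and leaving out both mice 2940 and 12145 kept 3.

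**Figure D1:**
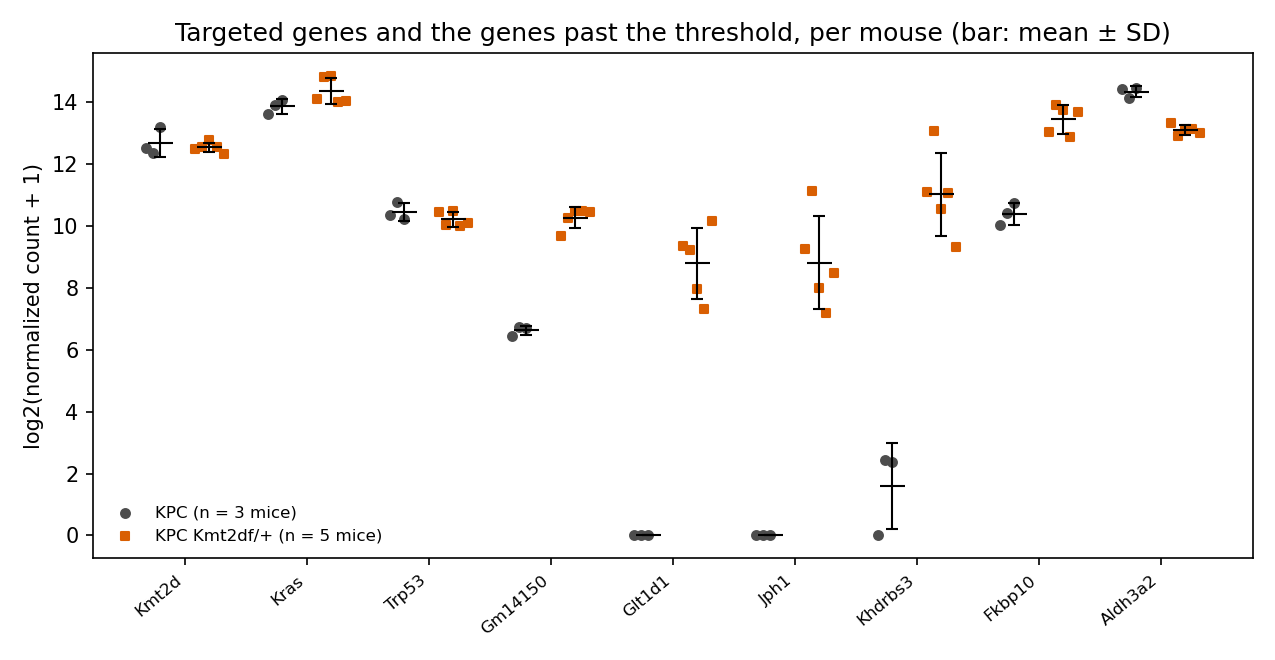
Expression of the 3 genes named by the genotypes and the 6 genes past the threshold, as log2(normalized count + 1) on the vertical axis, with 1 point per mouse (circles, 3 KPC mice; squares, 5 KPC Kmt2df/+ mice) and bars for the mean and SD. Kmt2d, Kras and Trp53 overlapped between the genotypes, whereas Glt1d1 and Jph1 were at 0 in every KPC mouse.

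These 6 genes, 5 higher and 1 lower, were those with a limma adjusted p below 0.05 among 16729 tested, and 9 passed at 0.10. At an unadjusted p below 0.05 there were 1993 genes, 1025 higher and 968 lower, where 836 would be counted on average if no gene differed. The groups did not overlap in 1564 genes, against 597 (3.57% of those tested) on average over all 56 splits, tied values aside. Genes are not independent, so a count can lie far from such an average. Other splits of the mice went higher, to 2960 genes at an unadjusted p below 0.05 and 1986 without overlap. Both of these came from the split of KPC Kmt2df/+ mice 2500, 2940 and 12145 from the rest. All KPC mice stay together in that split, so it is not free of genotype. Of 56 splits, the real one included, 3 reached the first count and 2 the second. The count of 6 changed when single mice were left out, which also leaves fewer mice to test. It was 0 without KPC mouse 12278, 2 without KPC mouse 3622, 3 without KPC Kmt2df/+ mouse 2500, and 13 without either mouse 12145 or mouse 12349. On whole reads recovered from the table, edgeR called 1 gene, the pseudogene Gm14150 (edgeR adjusted p = 0.0394), and not Fkbp10 (0.0651), Aldh3a2 (0.0651), Glt1d1 (0.226), Khdrbs3 (0.226) or Jph1 (0.329). On the same reads limma voom called 0 (1964 at an unadjusted p below 0.05) and DESeq2 called 437, of which 233 were higher. In simulated data with the spread of these lines, DESeq2 made 110 false calls among 253, limma 10 among 127 and edgeR 10 among 125, so the simulation does not favour the limma count of 6 over the edgeR count of 1.

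The genes next in order under the naming rule did not pass with limma, and DESeq2 called all of them. The rule admits only genes whose groups do not overlap, so the lack of overlap is no evidence for them. Over 21 other settings Tec passed in 6, Lrch2 in 5 and Pdxk in 3. Among those with higher values in KPC Kmt2df/+ lines, Lrch2 measured 2.8 ± 4 (0.5 without KPC mouse 3622, 4.2 without KPC mouse 12278) and 1679.6 ± 1355 (limma adjusted p = 0.0565), and Gli3, a transcription factor of the Hedgehog pathway, measured 121.2 ± 56.7 and 3298 ± 2553.3 (limma adjusted p = 0.179). Lpl, lipoprotein lipase, measured 30.5 ± 26.5 (15.2 without KPC mouse 2974) and 955.8 ± 701.3, and Pcdhb19, Otud4, Ppp1r14b, Hebp1 and Igsf10 completed the 12 genes, with limma adjusted p from 0.145 to 0.208. With lower values were Tec, a tyrosine kinase, at 2585.4 ± 390.4 and 570.8 ± 153.6 (limma adjusted p = 0.0525), and Pdxk, pyridoxal kinase, at 13538.3 ± 4446.7 and 3588.4 ± 657.7 (limma adjusted p = 0.0642). Nfe2l2, which encodes the NRF2 factor of the oxidative stress response, measured 43980.2 ± 6090.8 and 23228.8 ± 3492 (limma adjusted p = 0.208). Tmem8, Hagh, Neurl3, Il17rc, Galnt4, Isoc2a, Tpmt and Clec2d filled the remaining places, with limma adjusted p from 0.156 to 0.259.

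The third question was whether groups of genes moved together. With camera at a preset correlation of 0.01, 13 of the 33 lists tested passed, 6 higher and 7 lower in KPC Kmt2df/+ lines. None passed with an estimated correlation, where the lowest adjusted p = 0.501 with an estimated correlation. The lowest adjusted exact permutation p of the list scores was 0.236, which decides little, because a smallest possible p of 0.0179 over 33 lists could pass only if many lists reached it at once. No member of any list passed over all genes tested with limma, so the values below describe members without a limma call. DESeq2, over the same genes, called 43 list members, among them Sparc (adjusted p = 5.51e-06), Gli3 (1.2e-09), Ocln (0.000382), Nfe2l2 (0.000391), Btg2 (0.00178), Ccne1 (0.00294) and Cdc20 (0.0049). DESeq2 called 437 of all 16729 genes tested, and 1152 in the split of KPC Kmt2df/+ mice 2500, 2940 and 12145 from the rest. In the simulation 110 of its 253 calls were false, so these calls do not settle which members differ.

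All 32 G2/M genes had higher means in KPC Kmt2df/+ lines, with a median log2 difference of 0.45 (camera adjusted p = 2.79e-11 at the preset correlation; adjusted p = 0.531 with an estimated correlation). Adjusted over the list alone, 5 passed, against 0 over all genes tested. They were Cdc20, Kif20a, Ccnb1, Tacc3 and Cenpf. A camera p as small arose in 4 of 56 splits of the mice, the real one included, and the smallest was 5.7e-14. Cdc20, an activator of the anaphase-promoting complex, measured 12180.2 ± 826.3 and 18018.5 ± 1847.1, and Ccnb1, the mitotic cyclin B1, measured 23953.8 ± 2462 and 34977.7 ± 5015.6. The G2/M score per mouse was -0.25 ± 0.25 and 0.15 ± 0.18, without overlap (exact permutation p = 0.0179, the smallest the design allows). Of 32 S-phase genes 30 had higher means, with a median of 0.27 (camera adjusted p = 2.64e-05; adjusted p = 0.531 with an estimated correlation). Ccne1, cyclin E1, was the 1 gene that passed adjusted over the list alone, at 1898.6 ± 129.3 and 4720.1 ± 1701.1. The S-phase call ended without KPC mouse 3622 (camera adjusted p = 0.0668).

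Mesenchymal genes were the second group. Of 31 tested, 27 had higher means in KPC Kmt2df/+ lines, with a median log2 difference of 1.1 (camera adjusted p = 1.25e-06; adjusted p = 0.531 with an estimated correlation). Adjusted over the list alone 4 passed, against 0 over all genes tested. Sparc, a secreted matrix protein, measured 1270.4 ± 902.6 and 14557.4 ± 7248.2, and Cdh2, N-cadherin, measured 2930.4 ± 3670.8 and 17068.2 ± 3159.1. The KPC means were 833.3 for Sparc without mouse 2974 and 817.3 for Cdh2 without mouse 3622. The transcription factors Zeb2 and Prrx1 were the others. A camera p as small arose in 3 of 56 splits, with 8.01e-10 the smallest. The mesenchymal score was -0.99 ± 0.23 and 0.6 ± 0.78, without overlap (exact permutation p = 0.0357). Among 37 extracellular matrix genes 26 had higher means (camera adjusted p = 0.0488; adjusted p = 0.531 with an estimated correlation), and Vcan, versican, passed adjusted over the list alone, at 938.8 ± 604.2 (595 without KPC mouse 12278) and 4399.3 ± 1913. The matrix call was lost without any single mouse except KPC mouse 3622, with camera adjusted p from 0.0523 without mouse 2940 to 0.38 without KPC mouse 2974. It was also lost on ranks (0.062), with pseudocount 8 (0.0566), with a mean of at least 100 (0.154) and after quantile normalization (0.117).

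Lineage genes had lower means. Of 33 epithelial genes, 30 were lower, with a median log2 difference of -0.95 (camera adjusted p = 0.000284; adjusted p = 0.531 with an estimated correlation), and none passed adjusted over the list alone. Ocln, the tight-junction protein occludin, measured 5096.9 ± 2239.5 and 485.1 ± 332.6, and the epithelial factor Ehf measured 11354.4 ± 4756.6 and 780.6 ± 1209.4 (252.4 without mouse 12352). The epithelial score overlapped between the genotypes (exact permutation p = 0.161), and KPC Kmt2df/+ mouse 12349, at 1.06, lay within the KPC range. Of 34 genes of the classical pancreatic cancer subtype, 27 were lower, with a median of -1.52 (camera adjusted p = 0.000468; adjusted p = 0.531 with an estimated correlation). Their score also overlapped (exact permutation p = 0.179). Ductal and progenitor genes were lower in 16 of 19, among them Lgr5 at 1070 ± 378.4 and 189.2 ± 186.7, or 112.3 without mouse 12349 (camera adjusted p = 0.0449; adjusted p = 0.531 with an estimated correlation). This call ended without KPC mouse 3622 (camera adjusted p = 0.216), without mouse 12145 (0.081) and without mouse 2500 (0.0555), and also on ranks (0.0588), with array weights (0.088) and without processed pseudogenes (0.0513).

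Stress and metabolic lists followed. Genes of the NRF2 and glutathione list were lower in 22 of 24, with a median log2 difference of -0.66 (camera adjusted p = 7.79e-05; adjusted p = 0.501 with an estimated correlation), and Nfe2l2 passed adjusted over the list alone. Gclc, the catalytic subunit of glutamate-cysteine ligase, measured 30436.8 ± 5618.1 and 18829.5 ± 4738.2. Cholesterol synthesis genes were lower in 23 of 25, with a median of -0.38 (camera adjusted p = 0.000239; adjusted p = 0.531 with an estimated correlation), and Hmgcr, the rate-limiting reductase, measured 23912.9 ± 3322.1 and 19298.7 ± 1756.6. The p53 target list was lower in 23 of 33 (camera adjusted p = 0.0449; adjusted p = 0.501 with an estimated correlation), led by Btg2 at 10166.7 ± 3886.9 and 1695.1 ± 1035.7. Hypoxia genes were higher in 17 of 24 (camera adjusted p = 0.0212; adjusted p = 0.531 with an estimated correlation), led by Ak4 at 697.8 ± 350.8 and 2406.2 ± 1775.4. The p53 call was lost without mouse 12278 (0.0926), 3622 (0.0904), 2500 (0.0586), 12352 (0.0629) or 12349 (0.125), on ranks (0.0588), after quantile normalization (0.0602), with pseudocount 8 (0.0514) and without processed pseudogenes (0.0528). The hypoxia call was lost without mouse 2974 (0.0648), 12278 (0.0926), 2940 (0.0523) or 12145 (0.0682), without both of the last 2 (0.296) and with array weights (0.0674).

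Lists that reflect RNA or library composition moved as well. Mitochondrially encoded transcripts were lower in 13 of 15 (camera adjusted p = 0.00301; adjusted p = 0.501 with an estimated correlation) and took 1.86% to 2.32% of reads in KPC mice and 1.53% to 1.74% in KPC Kmt2df/+ mice. Ribosomal protein genes were higher in 41 of 50 (camera adjusted p = 0.00301; adjusted p = 0.646 with an estimated correlation), a call lost without KPC mouse 12278 (0.206), without mouse 2940 (0.143) and without mouse 12145 (0.0643). It also ended after quantile normalization (0.55) and with array weights (0.333), and without both mice 2940 and 12145 (0.741) the difference changed sign.

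**Figure D2:**
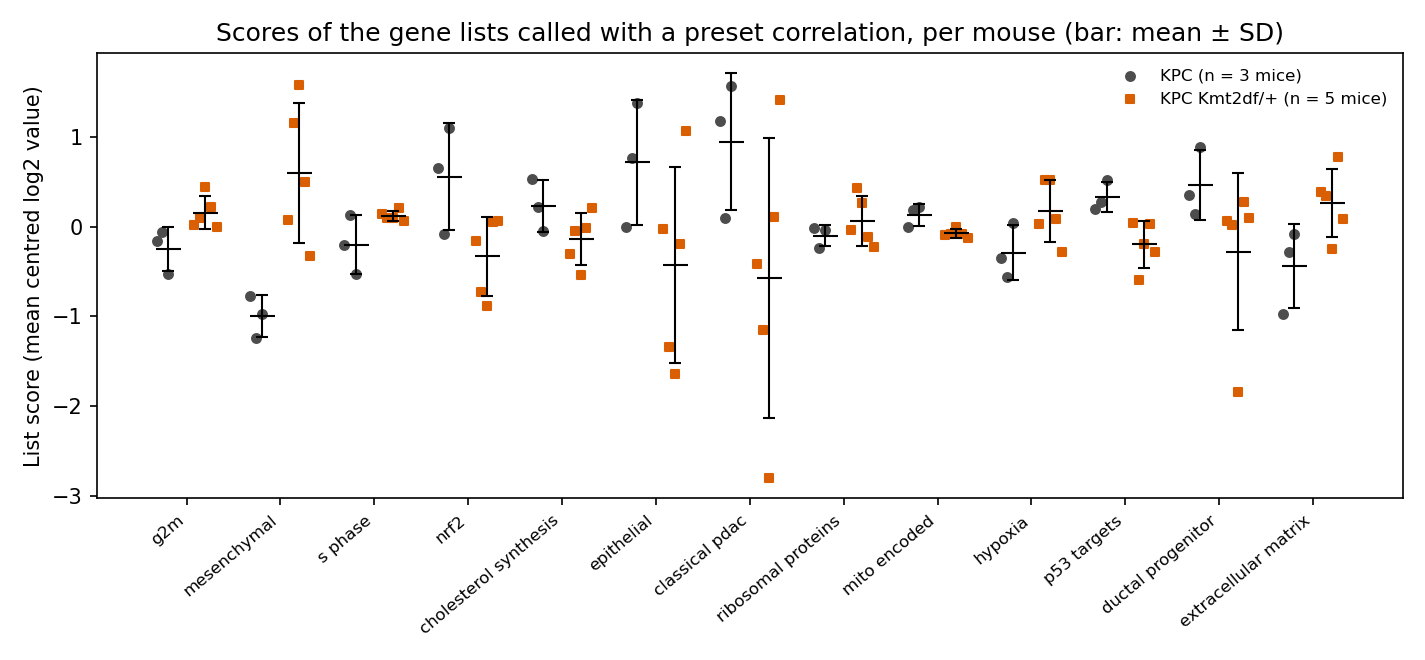
Scores of the 13 lists that passed at the preset correlation, as the mean centred log2 value of the list members on the vertical axis, with 1 point per mouse (circles, 3 KPC mice; squares, 5 KPC Kmt2df/+ mice) and bars for the mean and SD. The genotypes did not overlap for the G2/M, mesenchymal and p53 target scores, and mouse 12145 had the lowest classical subtype score, at -2.8.

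The other 20 lists did not pass at the preset correlation. The COMPASS methyltransferase list is broader than Kmt2d and its partners. It also holds Cxxc1 and the demethylase Kdm1a, which had the smallest unadjusted p of the list (limma p = 0.00639). The list had 12 of 20 genes higher and a median log2 difference of 0.06 (camera adjusted p = 0.225). Its score did not overlap (exact permutation p = 0.0179, adjusted p = 0.236) and fry called it (adjusted p = 0.0427). The fry test also called the p53 target and mitochondrially encoded lists. TGF-beta and activin genes were higher in 28 of 45 (camera adjusted p = 0.209), MAPK output genes lower in 22 of 37 (0.329), YAP targets higher in 17 of 27 (0.103), Wnt genes lower in 17 of 27 (0.309) and Notch genes lower in 12 of 18 (0.283). Interferon genes had a median log2 difference of -0.17 and a mean of 0.01 (0.423), and Hedgehog genes a median of 0.17 and a mean of -0.02 (0.458). Glycolysis (0.309), oxidative phosphorylation (0.892), fatty acid synthesis (0.745), the unfolded protein response (0.483), antigen presentation (0.103), cytokines (0.189), Hox genes (0.103) and basal-like subtype genes (0.508) did not pass either. Other settings added calls among these lists. YAP targets passed without mouse 12278 (camera adjusted p = 0.0388), 3622 (0.034) or 12145 (0.0202) and with array weights (0.0124), and Hox genes without mouse 12278 (0.0454), 12352 (0.0424) or 12349 (0.00905) and with no filter (0.00776). Without both mice 2940 and 12145, YAP targets (0.0188), TGF-beta and activin genes (0.0278), antigen presentation (0.0402) and interferon genes (0.0461, lower) passed. TGF-beta and activin genes passed without mouse 12145 (0.0376), cytokines without mouse 2974 (0.0135) and antigen presentation without mouse 2940 (0.0155). Adjusted over the list alone, 2 antigen presentation genes passed, H2-T23 and Tapbp, both with lower means. Single genes passed in this way in the Wnt (Dkk2), Hedgehog (Gli3) and fatty acid (Acaca) lists, all with higher means, and Stat2 (lower) and Ifit2 (higher) passed among interferon genes.

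Marker lists of other cell types did not pass with camera, whose adjusted p was 0.238 for leukocyte markers, 0.576 for endothelial, 0.329 for acinar and 0.309 for endocrine and neural markers. A second fry p, for change in either direction, did pass for the 7 endocrine and neural genes (adjusted p = 0.025). This second fry p was not particular to them. It also passed for the mitochondrially encoded (0.025), mesenchymal, extracellular matrix and fatty acid synthesis lists (0.0373 each). The G2/M, NRF2 and interferon lists passed with it too (0.0494 each). For the leukocyte, endothelial and acinar markers it was 0.84 to 0.875. Fibroblast markers and sex-linked genes had fewer than 5 tested members and were not tested as lists. Xist measured 54325.7 in KPC mouse 12278 and 56291.6, 36343.2 and 79439.1 in KPC Kmt2df/+ mice 12145, 12352 and 12349. In the other mice it was at most 10.3. The Y-linked Kdm5d measured 238.9 and 1414.7 in KPC mice 2974 and 3622, 4482.1 in KPC Kmt2df/+ mouse 2940 and at most 3.2 elsewhere. The genotypes were thus not balanced for these genes, and no test was adjusted for sex. The fibroblast genes that could be tested were Cthrc1, at 11.7 and 154.6 on average (96.6 in KPC Kmt2df/+ without mouse 12349) and past the threshold over these 3 genes alone, Pdgfrb, at 1.3 and 43.1, and Pdgfra, at 265.1 and 335. DESeq2 called Cthrc1 (adjusted p = 0.00815), Pdgfrb (0.0335) and the neural and endocrine transcription factor Pax6 (0.000403), all with higher means in KPC Kmt2df/+ lines. Pdgfrb and Pax6 did not rise in every line. Pdgfrb was 0 in mouse 2500. Pax6 was 2179.7 and 3222.1 in mice 2940 and 12145, 78 and 100.3 in 2500 and 12349, and 3.8 in 12352, against at most 4.3 in KPC.

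The last question was how far the lines followed genotype as a whole. The division by genotype took up 22.6% of the variance over the tested genes (pseudo-F 1.75, exact permutation p = 0.0536), which missed the threshold. Any division of so few mice takes up part of the variance by chance, so this share cannot all be credited to genotype. The first principal component, with 36.5% of the variance, was led by KPC Kmt2df/+ mice 12145, at 172.9, and 2940, at 90.4. The mean distance between lines was 178 within KPC and 201.8 within KPC Kmt2df/+, a difference within the spread of other groupings (exact permutation p = 0.75). Without mouse 12145 the difference changed sign, to -5.06.

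**Figure D3:**
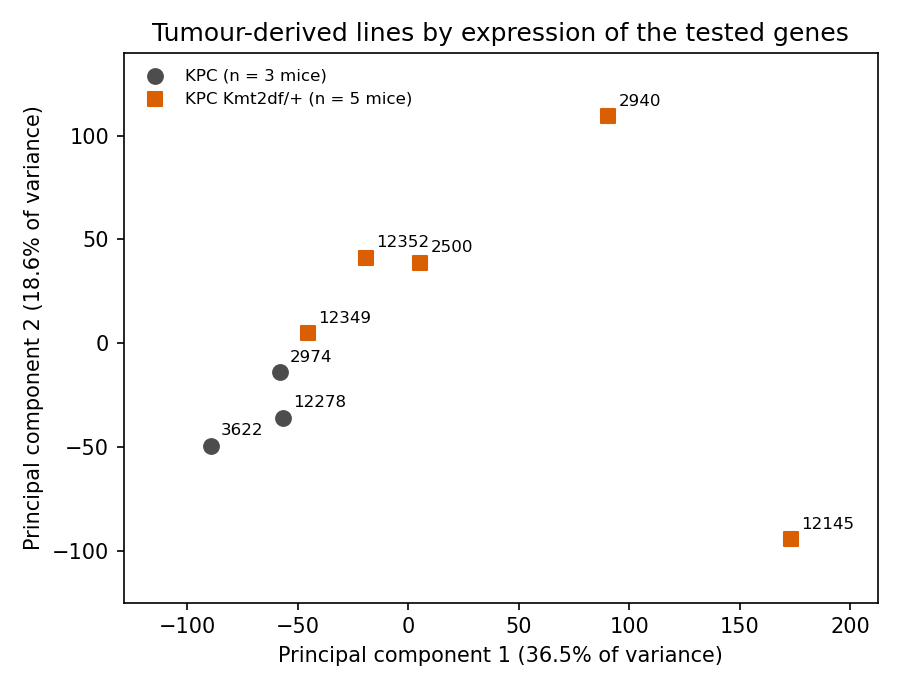
Positions of the 8 mice on the first 2 principal components of log2(normalized count + 1), with the share of variance on each axis (circles, 3 KPC mice; squares, 5 KPC Kmt2df/+ mice). Mouse 12145 lies at 172.9 on the first component and mouse 2940 at 90.4, away from the other 6 mice.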

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

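The tests in this part were chosen after the results had been seen, except the one of other scalings, which was set before its result. In the group of 5 KPC Kmt2df/+ mice, 112 results were looked at for a mouse far from the others, and 9 had one. About 6 would be counted by chance on average if the results were normally spread. Genes were judged here on normalized counts, not log2 values, and are not independent, so the 6 is only a rough guide. KPC was not examined, since it has 3 mice. Mouse 2940 stood above the others in Khdrbs3 (8609.7 against 644.0 to 2188.1) and in Jph1 (2228.2 against 145.3 to 616.5). Mouse 12145 stood below the others in the YAP target score (-0.92 against 0.2 to 0.5) and the ductal and progenitor score (-1.84 against 0.02 to 0.27), and above them in Ak4 (5556.6 against 1263.8 to 1878.8). Mouse 12352 stood above the others in Ehf (2893.6) and Timp1 (6933.9), mouse 12349 in Muc1 (22669.6) and mouse 2500 in Vcan (7746.0).

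The first pattern weighed is a set of genes silent in every KPC line and read in every KPC Kmt2df/+ line, and its standing depends on a cutoff. At the first cutoff looked at, a KPC mean below 2 and at least 20 in each KPC Kmt2df/+ mouse, there were 2 such genes, Glt1d1 and Jph1, and 8 of the 56 splits of the mice gave as many, up to 6, so a chance division of the lines could account for the count. A second cutoff, below 5 and at least 100, was set after the first had been seen; it adds Khdrbs3 and Lrch2, and of 56 splits only the real one, 1, reached 4 (highest other 2), but because 2 cutoffs were tried this count does not exclude chance. Lower depth is argued against, since at the lowest KPC Kmt2df/+ level of these genes at least 135.7 reads would have fallen in a KPC mouse. Of the 4 genes, 0 lie within 15 Mb of Kmt2d, a window set after the genes had been seen. Khdrbs3, at 68928420 to 69101211, does lie on chromosome 15 with Kmt2d. Silencing that differs from tumour to tumour and an effect of the Kmt2d genotype both stay open.

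The second pattern is the tubulin pseudogenes. All 5 tested processed pseudogenes with at least 97% identity to Tuba1b or Tuba1c had higher values in every KPC Kmt2df/+ mouse, against 9.4% of 1111 other processed pseudogenes with non-overlapping groups (one-sided Fisher exact p = 8.17e-06, on genes noticed for this pattern). A fixed share of the parents' reads is argued against, since the median log2 difference of the pseudogenes exceeded that of their parents by 1.19, and by more than 2 SE in 4 of the 5. Tuba1b and Tuba1c lie beside Kmt2d on chromosome 15, at 98931425 and 99029891, so a candidate explanation is that strain variants inherited with the modified allele send tubulin reads to the pseudogenes. The Fisher p cannot decide this, because the genes were noticed first and the table holds no read sequences; transcription of the pseudogenes themselves also stays open.

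The third pattern is the higher mesenchymal and lower epithelial means in KPC Kmt2df/+ lines. Stromal cells as the main source are argued against, although DESeq2 called the fibroblast markers Cthrc1 and Pdgfrb: the highest mean among Col1a1, Col1a2, Col3a1, Dcn and Lum was 227.8 in KPC Kmt2df/+ lines (Col1a2, of which mouse 12145 alone had 1037.5), while Sparc reached 14557.4. The authors' scaling is argued against too, since the mesenchymal score difference of 1.59 was at least 1.44 under 2 other scalings. Mice 2940 and 12145 do not carry the whole mesenchymal difference, which was 1.01 without them (exact permutation p = 0.1, the smallest 3 against 3 mice allow), but they carry most of the epithelial one, which went from -1.14 to -0.43 (exact permutation p = 0.5). Mice 2940 and 12145 also had the highest Kras, 28721 and 29438.1, against 12557.9 to 17469.7 in the other mice. Whether the mesenchymal and epithelial differences follow the Kras level was not tested. Differences between tumours unrelated to genotype stay open, because list calls as numerous arose in other splits.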

How the results depend on the processing

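Alternatives were set before the data were examined, except leaving out both 2940 and 12145 and leaving out processed pseudogenes, which were chosen after seeing the data. The fits on recovered reads rest on a step found in the values themselves. In exploration edgeR and DESeq2 were first run in other forms, so the final form of these fits was not set beforehand. No paired analysis was possible because the genotypes come from different mice, which the labels do not pair. The library-level fits were not run because the 3 libraries of a mouse share 1 column. The main count of 6 genes was 1 with edgeR, 437 with DESeq2 and 0 with limma voom (1964 at an unadjusted p below 0.05), and 0 to 13 when single mice were left out. The 6 genes were all among the 437. The cause was not tested. The count of 13 lists became 0 with an estimated correlation, 3 with fry for a single direction, 10 on ranks and 10 after quantile normalization. It was 13 with equal totals, 11 with pseudocount 8, 11 with array weights, 12 with a mean of at least 100 and 14 with no filter. It was 10 to 12 without single mice and 15 without 2940 and 12145. These counts can include lists outside the 13, such as the COMPASS list with fry and YAP targets without 2940 and 12145. Of the 13, fry called only the p53 target and mitochondrially encoded lists. The share of genes with higher values among those at unadjusted p below 0.05, 51.4%, was 44.5% with equal totals and 55.6% with quantile normalization. The separation of the genotypes passed in no setting where it could, at 20.9% to 28.5% of the variance without single mice; without 2940 and 12145 the smallest possible p is 0.1, so that setting decides nothing. The Kmt2d difference ranged from -0.32 to 0.1 without single mice. The difference in spread ranged from -5.06 to 36.57 without single mice and was -32.56 without 2940 and 12145.

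Lists and scores that changed sign had not passed in the main analysis, except ribosomal proteins. As scores, interferon was -0.16 with z-scores, -0.18 with the median and -0.08 with pseudocount 8; Hedgehog was 0.19, 0.08 and 0.05 in turn and 0.04 after quantile normalization; oxidative phosphorylation was 0.01 with the median. As lists relative to other genes, interferon was -0.02 with pseudocount 8, -0.15 with a mean of at least 100 and -0.05 with array weights; antigen presentation was 0.04 with no filter; oxidative phosphorylation was -0.05 after quantile normalization and -0.02 with array weights; Wnt was 0.04 and the unfolded protein response -0.02 with array weights. Without 2940 and 12145 the scores were interferon -0.34, Wnt 0.18, Hedgehog 0.29, unfolded protein response -0.26, leukocyte 0.19, endocrine and neural -0.61 and ribosomal -0.03. The lists were then interferon -0.36 (a call, camera adjusted p = 0.0461, in the direction camera gave in the main analysis, while the mean changed sign), oxidative phosphorylation -0.03, Wnt 0.16, unfolded protein response -0.28, leukocyte 0.18, endocrine and neural -0.63 and ribosomal -0.05.

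Without single mice the lists ranged from -0.08 to 0.4 (basal-like), -0.17 to 0.3 (interferon), -1.06 to 0.04 (cytokines), -0.28 to 0.15 (Wnt), -0.39 to 0.02 (Notch), -0.16 to 0.27 (Hedgehog), -0.63 to 0 (endothelial), -0.01 to 0.09 (oxidative phosphorylation) and -0.38 to 0 (antigen presentation). The scores ranged from -0.15 to 0.33 (basal-like), -0.05 to 0.01 (oxidative phosphorylation), -0.24 to 0.24 (interferon), -0.23 to 0.21 (Hedgehog), -0.37 to 0.07 (Wnt) and -0.05 to 0.36 (unfolded protein response). The cause of these changes was not tested.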

Other observations

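Every test in this part was chosen after the data had been seen, except the count of splits for DESeq2. Immediate-early genes, transcribed within minutes of a growth or stress stimulus, had lower means in KPC Kmt2df/+ lines in 19 of 25 genes of a list drawn up after Fos, Fosb, Egr3, Zfp36 and Btg2 had been noticed. The score of this list differed by -0.81 (exact permutation p = 0.0179, the smallest possible), without overlap between the genotypes, and camera gave p = 2e-04 at the preset correlation and p = 0.117 with an estimated correlation. Adjusted over the list alone 4 genes passed, Zfp36, Btg2, Egr3 and Fosb, and none passed over all genes tested with limma, where 7 had an unadjusted p below 0.05, while DESeq2 called these 4. Zfp36 differed by -2.32 on the log2 scale and Fos by -2.63. The list contains genes that prompted it, so its p is no independent evidence.

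Among TGF-beta family genes, Grem1, a BMP antagonist, measured 3145.2 ± 4816.7 in KPC and 24644.6 ± 23243.4 in KPC Kmt2df/+ lines, Fstl3, an activin antagonist, 158 ± 95.5 and 660.5 ± 231.9, and Inhba, an activin subunit, 566.2 ± 334.1 and 2948 ± 3247.9. The Grem1 means were 365.5 in KPC without mouse 2974 and 14428.6 in KPC Kmt2df/+ without mouse 2940, and Inhba was 1505.8 without mouse 2940. None passed over all genes tested with limma, while DESeq2 called Fstl3 (adjusted p = 0.00498) and Inhba (adjusted p = 0.0497). In mouse 2940 the cell-cycle inhibitors Cdkn2a and Cdkn2b had 0 reads, while the other 7 mice had 10436.6 to 17417.7 and 4927.3 to 11043.2, and the neighbouring gene Mtap measured 159752.8 there against 24287.1 to 45445.6 elsewhere. The same mouse had the highest Hox score, 4.22.

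Other splits of the mice were counted for each result over all genes. The real split called 6 genes with limma, and the highest of the other splits called 4, so 1 of 56 splits, the real one, gave as many. This is 1 of several counts made after the result, and the 6 fell to 0 without KPC mouse 12278 and with limma voom (1964 at an unadjusted p below 0.05; edgeR 1, DESeq2 437), so a chance division of the mice is not taken as excluded. The 1993 genes at an unadjusted p below 0.05 were reached by 3 of 56 splits (highest other 2960) and the 1564 without overlap by 2 (highest other 1986). DESeq2 called 437 genes in the real split, which 2 of 56 splits reached. The split of KPC Kmt2df/+ mice 2500, 2940 and 12145 from the rest called 1152, so DESeq2 made more calls there than in the division by genotype. The same split gave the counts of 2960 and 1986. All KPC mice stay together in it, so it is not free of genotype and does not show what an unrelated division yields. For lists, 7 of the 56 splits gave at least the 13 called with the preset correlation, up to 14, so chance cannot be excluded for the list calls. Within 3 Mb of Kmt2d, 17 of 91 tested genes (18.7%) had non-overlapping groups, against 9.3% elsewhere (two-sided Fisher exact p = 0.00556, over genes, which are not independent).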
